A study of Homo sapiens with 30 samples.

How the data were processed

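Gene expression was measured in the lymphoma cell lines TMD8 and U2932 on Illumina human bead arrays. Per the labels, RNA was extracted with an RNeasy kit, its integrity was checked, and biotin-labelled cRNA was made with the Ambion TotalPrep kit. GenomeStudio was used to read the arrays, with version and settings not given. Samples were grouped by cell line, treatment and time as the labels give them, into 10 groups of 3 arrays (30 arrays). Replicate numbers only tell arrays of a group apart, and no pairing, batch or slide is given in the labels. The TMD8 samples are listed in repeated runs of the same groups in the same order. Whether TMD8 arrays of the same number belong together was not tested, and no fit allowed for it.

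Both kinds of deposited values hold 47231 probes for each of the 30 samples. The deposited signal table holds bead summary signals in intensity units on a linear scale, neither normalized nor background corrected as far as the values show. The deposited series values are on a log2 scale; the log base was read from their range, as the labels state neither the base nor the normalization. The 12 TMD8 columns share 1 distribution of values (median 4.85) and the 18 U2932 columns another (median 6.42), so each line had been quantile normalized on its own. Columns were given to samples by their names alone. As the names of the U2932 arrays differ between the tables, each comparison was run with the signal table's names, as planned, and with the value table's names. The runs with the value table's names used that table's own log2 values. They were fitted for each line on its own, apart from the differences between lines. Names, normalization and arrays fitted thus change together, and the effect of the names alone was not isolated.

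Probe identifiers gave 1 symbol for 30113 probes, several for 8 and none for 17110, and 30074 symbols were matched to a RefSeq gene table by gene ID. The planned background correction (neqc) needs detection p-values or control probes, which the signal table lacks. A stand-in was used, chosen after the values had been examined: on each array the background was placed at the mode of the log2 density, its spread came from the signals below the mode, and normexp correction, an offset of 16, quantile normalization over all 30 arrays and log2 followed. The detection p was the upper tail of that background. A first fit with plain normexp, and its calls, had been seen before the stand-in was settled; plain normexp with an offset of 50 is among the alternatives. On simulated data the background step called 4.89% of background probes and 98.3% of signal probes detected. The simulated background followed the normal curve that the step assumes, so the first share was nearly fixed in advance. The simulated signals lay far above their background, so the second share does not cover arrays of low signal.

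Probes were kept if detected at p under 0.05 on all arrays of at least 1 group (25382 probes), and the brightest kept probe stood for each gene. This left 20625 features, of which 13124 were named genes and 7501 were unnamed probes. One linear model with a mean per group was fitted to the 30 arrays with limma 3.58.1 in R 4.3.3 (20 residual degrees of freedom, eBayes without trend or robust options). The 15 contrasts were tested two-sided with Benjamini-Hochberg adjustment over the features, and a feature was called at an adjusted p under 0.05. Counts at an unadjusted p under 0.05 are to be read against those expected by chance. These are 1031 of the 20625 features, 964 in the fit of TMD8 alone and 854 in that of U2932 alone. Differences between lines are TMD8 minus U2932, and between times 8 h minus 4 h. Where a gene named in a comparison of 2 groups lay above background on none of the arrays of 1 group, its fold was computed against the background level and given as a bound. Intervals are at 95%. Number of arrays limits the precision: in data simulated with 3 arrays per group, the TMD8 comparison at 8 h recovered 48% of changes of log2 1 and 96% of log2 2 in the fit of 30 arrays, and 68% and 95% in the TMD8 fit.

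The named genes follow a rule set before the data were examined. For each treatment comparison these are the 10 called genes with the largest increase and the 10 with the largest decrease among those whose 3 arrays of 1 group all lie above the 3 of the other. For each difference between lines or times they are the 5 largest each way, and in every comparison the called members of fixed gene lists (as examples) and SPIB, IRF4, MYC and DHX9. Unnamed probes were counted and not named. The snoRNAs, and genes ranked under the value table's names by the same rule, were chosen after the values were seen.

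The 29 gene lists (814 symbols, 762 matched to the arrays) were also written before the data were examined. They cover mitosis, DNA replication, tubulins, ETS family, ABC-type and GCB-type lymphoma, NF-kB targets, interferon, B cell receptor and identity, HLA class II, plasma cell, immediate early, MYC targets, p53 targets, apoptosis, integrated stress response, unfolded protein response, heat shock, hypoxia and glycolysis, oxidative stress, cholesterol synthesis, histones, mRNA splicing, cytosolic ribosome, mitochondrial respiration, actin and SRF targets, and markers of T cells, myeloid cells and stromal or epithelial cells. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. In simulated data a list raised by log2 0.3 was called and 0 other lists were. Genes varied independently there, so this does not test false calls of lists whose members vary together.

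Correlations of log2 differences are across features. For treatments that share DMSO arrays, 100 simulations of unchanged groups gave the correlation and covariance that sharing alone produces where all groups vary alike. The alternatives were no background correction, plain normexp, median scaling, the deposited log2 values, no detection filter, a stricter filter (p under 0.01 on all 30 arrays), each line normalized and fitted on its own (19284 features in TMD8, 17083 in U2932), the mean of a gene's probes, a fold minimum of 0.58 log2, an intensity trend with a robust prior, and each array left out in turn. A fit without arrays of mean signal under 200 was added after seeing the data; that limit was also chosen then. A slide block was not run, as no slide is given. No array had signals identical to another's.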

Results

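Expression was measured on 30 bead arrays from the human lymphoma cell lines TMD8 and U2932, both of the activated B cell-like (ABC) type of diffuse large B cell lymphoma. Cells had received YK-S or YK-R, which the labels list as separate treatments and which are the mirror-image forms of YK-4-279, a small molecule made to block ETS-family transcription factors, with the S form known as the active one. U2932 also had arrays from cells given DMSO, the solvent, and TMD8 had none. The 10 groups of 3 arrays were TMD8 with YK-S or YK-R at 4 h and 8 h, and U2932 with DMSO, YK-R or YK-S at 4 h and 8 h. The labels give no dose and do not say whether the 3 arrays of a group came from separate cultures, so the p-values may measure technical spread.

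The TMD8 arrays were bright and alike, with mean signals from 419.6 to 494.1 and 46.6% to 56.1% of probes above background. The U2932 arrays ranged from 85.4 to 340.9, with 25.2% to 50.5% of probes above background. A mean signal under 200, a limit set after the values were seen, was found on 8 arrays, all from U2932. DMSO 4 h replicate 1 lies just under it, at 196.7 with 47.3% of probes above background. By the sample names of the deposited signal table these were 3 DMSO arrays and 3 YK-R arrays at 4 h, 1 YK-S array at 4 h and 1 YK-S array at 8 h. By the names of the deposited log2 table they were 2 arrays of each 4 h group, 1 YK-R array at 8 h and 1 YK-S array at 8 h. The number of arrays limits the precision: the 95% interval of a difference reached a median of 0.53 log2 to either side.

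**Figure D1:**
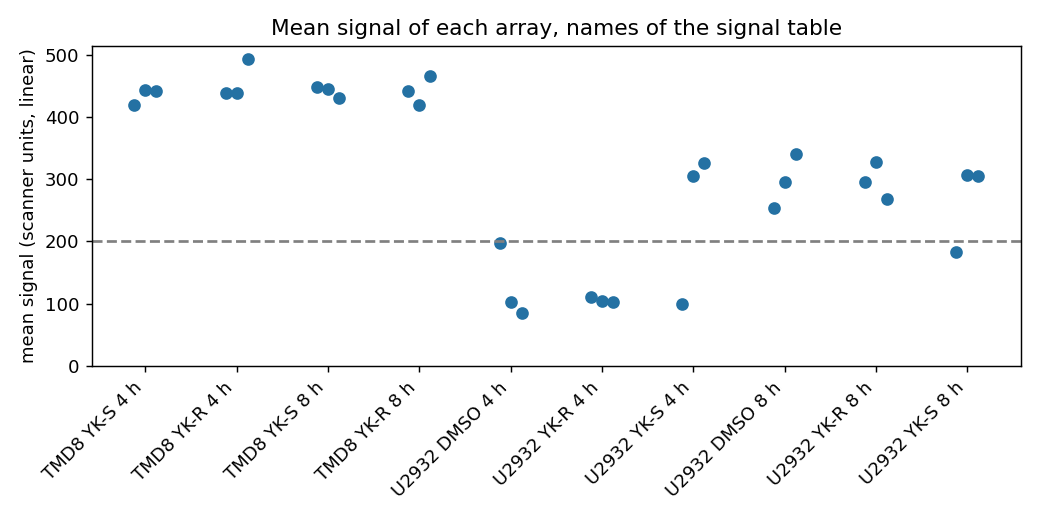
Mean signal of each of the 30 arrays on a linear scale (y axis, scanner units) by group (x axis), with names from the signal table. Each point is 1 array, and the dashed line at 200 is the limit under which an array is called dim. The TMD8 arrays sit between 419.6 and 494.1, and the 8 points under the line are all U2932 arrays.

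The deposited signal table and the deposited table of log2 values gave the same sample name to the same array for 12 of 12 TMD8 arrays. For U2932 they did so for 0 of 18 arrays. Each U2932 column of the log2 table ranked the probes as a differently named column of the signal table did, with rank correlations across probes of at least 0.999996, against 0.597 to 0.900 for the column of its own name. The group was the same under both names for 5 arrays and another one for 13. Which names are right was not settled, so U2932 results are given under the signal table's names first and then under the value table's names. Treatment comparisons under the value table's names also rest on its own normalization and on a fit of U2932 alone. The grouping of TMD8 arrays does not depend on this, but the spread per feature in the fit of all 30 arrays does.

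Whether the mirror-image forms of the compound act differently was tested in TMD8 by YK-S minus YK-R. At 8 h 12 small nucleolar RNAs (snoRNAs) of the C/D box class, which guide methylation of ribosomal RNA, were called as higher with YK-S in a fit of TMD8 alone, and none in the planned fit of all 30 arrays. Fitted on the 12 TMD8 arrays alone, 13 features were called: 12 were C/D box snoRNAs, all higher with YK-S, and 1 was an unnamed probe that was lower. SNORD46 (probe ILMN_1682402) measured 11.36 ± 0.46 log2 with YK-S and 8.56 ± 0.41 with YK-R (SD, n = 3 each), a 6.92-fold difference, log2 2.79 (SE 0.28, limma adjusted p = 0.0057). SNORD38B (probe ILMN_1741944) was 7.06-fold higher, log2 2.82 (SE 0.34, limma adjusted p = 0.012), and lay above background on 3 of 3 YK-S and 2 of 3 YK-R arrays, so its fold rests on YK-R values near the background. The other called snoRNAs were SNORD18A at log2 2.56, SNORD71 at 1.99, SNORD105 at 1.96, SNORD13 at 1.94, SNORD2 at 1.85, SNORD83B at 1.79, SNORD117 at 1.62, SNORD59B at 1.60, SNORD68 at 1.48 and SNORD35A at 1.42. SNORD105 lay above background on 1 of 3 YK-R arrays and SNORD2 on 2 of 3, so their values also rest on YK-R signals near the background. The class was singled out after its values were seen, and no set test was run on it. Whether these probes read the mature snoRNA or a longer RNA that holds its sequence was not tested.

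Over the 101 C/D box snoRNAs measured in the TMD8 fit the median log2 difference at 8 h was 0.37, and 80 of them were above 0. In the fit of all 30 arrays the median over 103 was 0.25, with 82 above 0. The 81 H/ACA box snoRNAs, which guide pseudouridylation, had a median of 0.10 with 52 above 0 and none called. The fit of all 30 arrays together, which was the planned one, called 0 features at 8 h (495 at an unadjusted p under 0.05, against 1031 expected by chance), with SNORD46 at log2 2.82 (SE 0.77, limma adjusted p = 0.50) and SNORD38B at 2.03 (SE 0.45, limma adjusted p = 0.30). The deposited log2 values, fitted on the TMD8 arrays alone, also gave 13 calls, 12 higher. That fit repeats the TMD8 fit on the same arrays, so it is no separate check of the fit of 30 arrays. In the TMD8 fit the count was 0 without YK-S 8 h replicate 2, 1 without YK-S replicate 3, 4 without YK-R replicate 3, 5 without YK-R replicate 1 and 279 without YK-R replicate 2, of which 28 were higher and 251 lower. Median scaling of all 30 arrays gave 24 higher and 41 lower, with the median of all features moved by 0.15. Over these TMD8 fits without 1 array the median of the C/D box class stayed between 0.25 and 0.41, and in the fit of 30 arrays between 0.20 and 0.30.

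At 4 h no feature passed in TMD8, with 56 at an unadjusted p under 0.05 in the fit of 30 arrays and 419 in the TMD8 fit. By chance 1031 and 964 are expected, so the p-values may be too large, and 0 calls do not show that nothing differs. SNORD38B at log2 2.24 (SE 0.34) and SNORD46 at 2.01 (SE 0.28) had limma adjusted p = 0.13 in the TMD8 fit, and the 3 YK-S arrays lay above the 3 YK-R arrays for both. The C/D box median was 0.087 at 4 h. The difference between 8 h and 4 h was called for 0 features in TMD8 (193 at an unadjusted p under 0.05, and 0 and 832 in the TMD8 fit), so a change of the effect with time was not shown for any single feature.

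**Figure D2:**
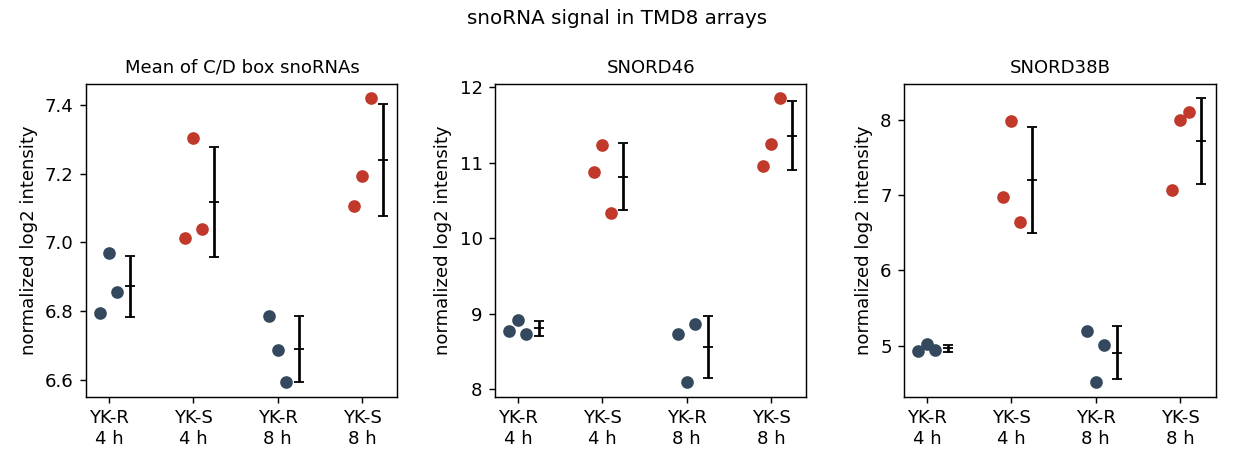
Normalized log2 intensity (y axes) in the 12 TMD8 arrays, normalized without U2932, by treatment and time (x axes), for the mean of the C/D box snoRNAs, SNORD46 and SNORD38B. Points are single arrays, and bars show the mean and SD of 3. At 8 h SNORD46 averaged 11.36 with YK-S and 8.56 with YK-R.

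Genes of mitosis were slightly higher with YK-S than with YK-R in TMD8 at 8 h. Of 37 measured members 34 were above 0, with a median log2 difference of 0.17, and the list was called by camera (adjusted p = 8.1e-05). With an estimated correlation the adjusted p was 0.99. No member passed the gene test, over all features or adjusted over the list alone. CDC20, the activator of the anaphase-promoting complex, was at 0.35 (SE 0.29), cyclin B1 (CCNB1) at 0.35 (SE 0.27), the spindle kinesin KIF2C at 0.34 (SE 0.21) and the checkpoint kinase TTK at 0.34 (SE 0.21). The median was 0.065 without YK-R 8 h replicate 1 and 0.068 without YK-S 8 h replicate 3, and the list was not called in either case (adjusted p = 0.37 and 0.46). At 4 h the mitosis list had 28 of 37 members above 0 and a median of 0.053, and was not called (adjusted p = 0.25).

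The other lists tied to the compound or the disease were not called in TMD8. At 8 h the ETS family had a median of -0.0034 with 10 of 21 above 0 (adjusted p = 0.94), tubulins 0.0054 with 9 of 16 above 0 (adjusted p = 0.94), NF-kB targets -0.047 with 9 of 30 above 0 (adjusted p = 0.94) and genes of ABC-type lymphoma -0.061 with 7 of 24 above 0 (adjusted p = 0.42). No member of these lists passed the gene test. Markers of T cells, with a median of -0.084 over 7, of myeloid cells, 0.041 over 5, and of stromal and epithelial cells, 0.030 over 8, were not called either (adjusted p of 0.42, 0.82 and 0.84).

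SPIB, the ETS factor named in the series title, was strongly expressed in TMD8 and showed no detectable difference between the forms. It measured 10.90 ± 0.13 with YK-S and 10.90 ± 0.13 with YK-R at 4 h (log2, SD, n = 3 each), and the 95% interval of the log2 difference was -0.68 to 0.67. At 8 h the interval was -0.71 to 0.63 around -0.042. The TMD8 fit, whose spread does not include U2932 arrays, gave narrower intervals for SPIB, -0.33 to 0.33 at 4 h and -0.37 to 0.29 at 8 h. IRF4, a survival factor of ABC-type lymphoma, was at -0.078 (-0.69 to 0.53) at 4 h and -0.11 (-0.72 to 0.50) at 8 h. MYC was at 0.17 (-0.52 to 0.86) and -0.18 (-0.87 to 0.51), and DHX9, the RNA helicase A, at -0.25 (-1.10 to 0.59) and -0.046 (-0.89 to 0.80), with -0.67 to 0.19 and -0.48 to 0.39 for DHX9 in the TMD8 fit. In U2932 SPIB was lower in level, at 8.15 ± 0.66 with DMSO at 4 h (SD, n = 3), and YK-S minus DMSO was -0.45 (-1.12 to 0.22) at 4 h and 0.89 (0.22 to 1.56) at 8 h, or 0.35 without the dim YK-S 8 h replicate 1, under the signal table's names, against -0.32 (SE 0.34) and 0.48 (SE 0.34) under the value table's. YK-R minus DMSO was -0.18 (-0.85 to 0.49) and 0.31 (-0.36 to 0.98), against -0.17 and -0.18 (SE 0.34 each), the latter of opposite sign. None of these 4 genes was called in TMD8 or in any U2932 comparison of treatments, under either naming.

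**Figure D3:**
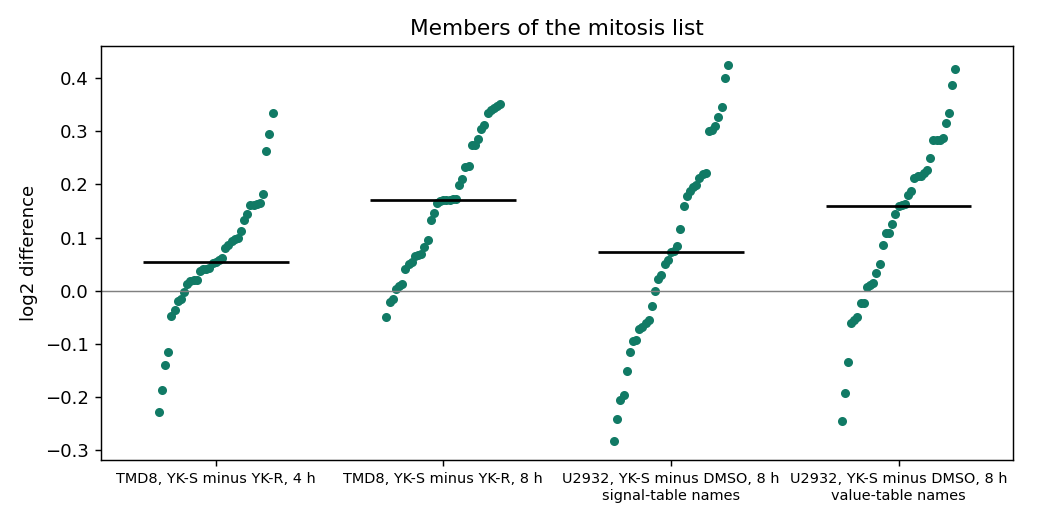
Log2 difference (y axis) of each of the 37 measured members of the mitosis list, sorted within each comparison (x axis), with the median as a line. The TMD8 8 h median is 0.17, and the U2932 8 h median of YK-S minus DMSO is 0.073 with the signal table's names and 0.16 with the value table's names.

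YK-S was compared with DMSO in U2932 to find genes that the S form changes. At 4 h, under the signal table's names, 1337 features were called, 773 higher and 564 lower with YK-S. RUNX2, a runt-family transcription factor, rose by log2 1.93 (SE 0.42, limma adjusted p = 0.0087), the extracellular matrix gene FBLN1 by 1.74 (SE 0.27), the lymphocyte receptor gene SLAMF1 by 1.73 (SE 0.33), and WWP2, a ubiquitin ligase, by 1.78 (SE 0.35). The SEs pool the spread of all groups. For RUNX2 the SD over 3 arrays was 1.31 with DMSO and 0.14 with YK-S, so its p-value may be too small. Of the genes named in this paragraph only FBXL6, with an SD of 0.78 with DMSO and 1.08 with YK-S, varied less with DMSO. The p-values of the others may thus be too small as well. Also among the 10 largest increases were GPR18 at 1.73, RPRD1B at 1.72, BEX4 at 1.63, MSRB2 at 1.60, CCZ1B at 1.57 and EFCAB14 at 1.57. The 10 largest decreases were ZBBX at -1.77, NRK at -1.73, FBXL6 at -1.72, ALOXE3 at -1.71, the Fc receptor gene FCGR2A at -1.71, SNORA58 at -1.67, CLEC17A at -1.63, AIFM3 at -1.62, ATP1B2 at -1.59 and NMNAT1 at -1.56. Of the 6 among these genes with another kept probe, 4 had one that moved the other way: RUNX2 at -0.41, WWP2 at -0.43, FBLN1 at -0.60 and FBXL6 at 0.26.

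By list, 3 of 21 ETS family genes rose and 0 fell with YK-S at 4 h, both over all features and adjusted over the list alone: ETS2 by 1.27 (SE 0.25), GABPA by 1.14 (SE 0.35) and ETV6 by 1.06 (SE 0.29). Of 16 plasma cell genes 3 rose (5 adjusted over the list alone), namely PRDM1, a driver of plasma cell differentiation, by 1.43 (SE 0.29), ELL2 by 1.06 (SE 0.28) and the plasma cell surface gene SDC1 by 1.05 (SE 0.29). Of 20 genes of the unfolded protein response 3 rose (4 adjusted over the list alone), namely the chaperone genes PDIA4 by 1.33 (SE 0.28) and DNAJC3 by 0.90 (SE 0.25), and EDEM1 by 1.10 (SE 0.26). TUBE1 rose by 0.90 among 16 tubulins, FCGR2B by 1.02 among 28 B cell receptor and identity genes, and TOP2A fell by 0.86 among 37 mitosis genes, each also adjusted over the list alone. With median scaling TOP2A had the opposite sign, at 0.66, above the shift of 0.46 in the median of all features. None of the 29 lists was called at 4 h: the lowest adjusted p was 0.302, shared by plasma cell, unfolded protein response and p53 target genes. ETS2, PDIA4, PRDM1 and TOP2A moved the same way without the compound, in DMSO at 8 h against these DMSO 4 h arrays (values below). Their changes thus cannot be told apart from a difference that lies in the DMSO 4 h arrays.

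These 4 h calls did not hold with the value table, where names, normalization and the arrays fitted all differ. The compared groups also differ in brightness, with 3 of 3 DMSO and 1 of 3 YK-S arrays dim. Under the value table's names 0 features were called (1916 at an unadjusted p under 0.05), with RUNX2 at 0.086 (SE 0.29), and WWP2, EFCAB14, ZBBX and PDIA4 had the opposite sign. With the signal table's names kept, a fit of U2932 alone called 0 as well (3234), so the loss of calls cannot be put down to the names. There 19 of the 20 genes with the largest changes kept their sign, with a median ratio of 0.786 to the log2 differences above. The exception, FBXL6 at 0.18, is read there from another probe (ILMN_1799389). These genes had been chosen for large, separated changes on the same arrays, so the kept signs were nearly fixed in advance and decide nothing. A stricter detection filter gave 112 and median scaling 3151 (3150 higher, 1 lower), and the count was 195 without DMSO 4 h replicate 2 and 6561 without replicate 3. As a list, hypoxia and glycolysis genes were lower with YK-S at 4 h under the value table's names, with 20 of 28 below 0 and a median of -0.085 (adjusted p = 0.036, and adjusted p = 0.56 with an estimated correlation). No member passed over all features, and 3 fell adjusted over the list alone.

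At 8 h YK-S and DMSO differed in 0 features in U2932, with 923 at an unadjusted p under 0.05 under the signal table's names and 186 under the value table's. Genes of the integrated stress response had a median log2 difference of -0.22, with 23 of 30 below 0 (camera adjusted p = 0.0056, and adjusted p = 0.73 with an estimated correlation), or -0.11 without DMSO 8 h replicate 1 (adjusted p = 0.11). Under the value table's names this list was at -0.047 (adjusted p = 0.28). There the mitosis list was called as higher with YK-S, with 29 of 37 above 0 and a median of 0.16 (adjusted p = 9.5e-08, and adjusted p = 0.29 with an estimated correlation). DNA replication was lower, with 24 of 35 below 0 and a median of -0.088 (adjusted p = 0.0045, and adjusted p = 0.63 with an estimated correlation). B cell receptor and identity genes were higher, with 21 of 28 above 0 and a median of 0.054 (adjusted p = 0.014, and adjusted p = 0.16 with an estimated correlation). Without dim arrays the latter pair of lists was not called, with DNA replication at -0.0047 (adjusted p = 0.12) and B cell receptor and identity genes at 0.044 (adjusted p = 0.13). No member of these lists passed the gene test at 8 h.

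YK-R was compared with DMSO in U2932 as the response to the other form. At 4 h, under the signal table's names, 3381 features were called, 1562 higher and 1819 lower with YK-R. BCL10, an adaptor of antigen receptor signalling to NF-kB, rose by 1.83 (SE 0.23, limma adjusted p = 0.00015), the cap-binding factor EIF4E by 1.74 (SE 0.38) and the survival gene BCL2A1 by 1.74 (SE 0.45). ZNF543 at 1.83, P2RY12 at 1.81, FERRY3 at 1.77, FBLN1 at 1.73, CCZ1B at 1.68, GPR18 at 1.65 and RPRD1B at 1.62 completed the 10 largest increases. The 18S ribosomal RNA gene RNA18SN5 fell by 2.72 (SE 0.77), CTDP1 by 2.14 (SE 0.42) and MID1IP1 by 2.06 (SE 0.35). The remaining 7 largest decreases were of probes above background on none of the YK-R arrays, so only bounds can be given: FBXL6 was at least 3.21-fold lower, FBXW5 2.99-fold, ZBBX 2.58-fold, NRK 2.42-fold, FHIP2B 2.37-fold, HOXD3 2.13-fold and GSDMA 1.86-fold. Of the 8 among these 20 genes with another kept probe, 5 had one that moved the other way. These were BCL10 at -0.89, FBLN1 at -0.88, EIF4E at -0.065, CTDP1 at 0.39 and FBXL6 at 0.25. Of these 20 genes only BCL2A1 and FBLN1 varied less over the DMSO than over the YK-R arrays. P2RY12, for example, had an SD of 1.36 with DMSO and 0.064 with YK-R. As the SEs pool the spread of all groups, the p-values of the others may be too small.

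By list, 2 of 21 ETS family genes rose with YK-R at 4 h and 0 fell, ETS2 by 1.22 (SE 0.25) and GABPA by 1.11 (SE 0.35), with the same count adjusted over the list alone. Of 16 plasma cell genes 3 rose, PRDM1 by 1.21 (SE 0.29), ELL2 by 1.08 (SE 0.28) and CD38 by 0.73 (SE 0.20), with the same count adjusted over the list alone. Among 30 NF-kB targets BCL2A1 and REL, at 1.22, rose and PLEK fell by 0.86, with 1 and 0 adjusted over the list alone. Among 28 B cell receptor and identity genes the kinase genes BLK and SYK fell by 1.23 and 0.60, and FCGR2B rose by 0.79, with 1 lower and 0 higher adjusted over the list alone. TUBD1 and TUBE1 rose by 0.95 and 0.97 and TUBB3 fell by 1.35 among 16 tubulins, with 3 higher and 1 lower adjusted over the list alone. CDC25C and CENPA rose by 0.88 and 0.71 and TOP2A fell by 0.77 among 37 mitosis genes, and EDEM1 rose by 0.98 among 20 genes of the unfolded protein response, with the same counts adjusted over the list alone. With median scaling, which moved the median of all features by -0.086, ELL2 was at -0.024. ETS2, PRDM1, TUBD1 and TOP2A moved the same way in DMSO at 8 h against these DMSO 4 h arrays (values below). For them too, an effect of YK-R and a difference in the DMSO 4 h arrays cannot be told apart. None of the 29 lists was called.

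Under the value table's names 306 features were called at 4 h, 93 higher and 213 lower with YK-R, and 0 of them were among the 3381. Of the 20 genes with the largest changes above, only EIF4E, BCL2A1 and RNA18SN5 kept their sign. The log2 differences under the 2 namings correlated at r = -0.377 across features, which are not independent replicates. The largest changes there were a rise of the kinase gene MAP2K3 by 1.06 (SE 0.15) and a log2 difference of -1.13 (SE 0.22) for UCP2, a mitochondrial carrier gene, against 0.16 and -0.077 under the signal table's names. Hypoxia and glycolysis genes were lower as a list, with 18 of 28 below 0 and a median of -0.14 (adjusted p = 0.026, and adjusted p = 0.30 with an estimated correlation), and 4 members fell, with 7 adjusted over the list alone. Oxidative stress genes were lower too, with 13 of 15 below 0 and a median of -0.17 (adjusted p = 0.032, and adjusted p = 0.30 with an estimated correlation), and 1 member fell, with 2 adjusted over the list alone. Under the signal table's names the U2932 fit called 347 features, 16 of the 20 genes above among them with the same sign. Of the 20, 19 kept their sign, with a median ratio of 0.775, and FBXL6, read from another probe, was at 0.18. Here too the genes had been chosen on the same arrays, so the kept signs decide nothing. A stricter detection filter gave 752 and median scaling 0, and leaving out DMSO 4 h replicate 2 or 3 gave 928 or 7868.

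At 8 h YK-R and DMSO differed in 0 features, with 206 at an unadjusted p under 0.05 (241 under the value table's names). Immediate early genes had a median of -0.17 with 21 of 28 below 0 (adjusted p = 0.0092, and adjusted p = 0.98 with an estimated correlation). Genes of the unfolded protein response had a median of -0.16 with 18 of 20 below 0 (adjusted p = 0.0092, and adjusted p = 0.26 with an estimated correlation). Without DMSO 8 h replicate 1 neither list was called, with medians of -0.024 and -0.045 (adjusted p = 0.78 for both). Immediate early genes were at -0.098 without YK-R 8 h replicate 2 (adjusted p = 0.16), and the unfolded protein response at -0.14 without YK-R 8 h replicate 1 (adjusted p = 0.064). With all arrays and the value table's names, the medians of immediate early and unfolded protein response genes were -0.014 and 0.0080. There MYC targets were higher, with 26 of 32 above 0 and a median of 0.072 (adjusted p = 0.015, and adjusted p = 0.10 with an estimated correlation), but at 0.028 and not called without dim arrays (adjusted p = 0.47). No member of these 3 lists passed the gene test.

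The forms were compared directly in U2932 by YK-S minus YK-R. At 4 h, under the signal table's names, 27 features were called, 19 higher and 8 lower with YK-S. Most named genes with higher values lay above background on none of the YK-R arrays. By these names 3 of 3 YK-R and 1 of 3 YK-S arrays at 4 h are dim, so array brightness and the form given cannot be told apart. The microRNA gene MIR146A was at least 1.69-fold higher with YK-S, MACO1 1.78-fold, C10orf88 1.57-fold, TEF 1.47-fold, OR11H1 1.36-fold, GDF11 1.22-fold, B3GLCT 1.22-fold, the stress gene SESN2 1.07-fold and TBC1D9 1.03-fold, each an at-least value. ATG9A, which acts in autophagy, rose by log2 1.18 (SE 0.19), and ANKRD24 fell by 1.20 (SE 0.23) and RIMS4 by 1.18 (SE 0.21). Another kept probe of ATG9A moved the other way, at -0.15, and another of GDF11 the same way, at 0.62. The mitosis list was lower with YK-S, with 34 of 37 below 0 and a median of -0.24 (adjusted p = 1.3e-05, and adjusted p = 0.79 with an estimated correlation), but at 1.05 with median scaling, which moved the median of all features by 0.64.

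Under the value table's names 0 features were called at 4 h (2280 at an unadjusted p under 0.05), all 12 named genes had the opposite sign, and the mitosis median was 0.19 (adjusted p = 0.10). The stricter detection filter, median scaling and the U2932 fit also gave 0 calls, and without YK-S 4 h replicate 1 the count was 167. At 8 h the forms differed in 0 features under either naming, with 463 and 505 at an unadjusted p under 0.05. The mitosis list was at -0.033 under the signal table's names (adjusted p = 0.95) and at 0.15 under the value table's names, with 24 of 37 above 0 (adjusted p = 0.0045, and adjusted p = 0.62 with an estimated correlation). The difference between lines of YK-S minus YK-R was called for 0 features at 4 h (615 at an unadjusted p under 0.05) and at 8 h (323). The mitosis list differed between lines, TMD8 minus U2932, by a median of 0.33 at 4 h (adjusted p = 4.3e-07, and adjusted p = 0.58 with an estimated correlation) and 0.15 at 8 h (adjusted p = 0.025, and adjusted p = 0.98 with an estimated correlation). The 4 h value was -0.057 under the value table's names and -1.09 with median scaling, which moved all features by -0.72.

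Log2 differences of YK-S minus YK-R correlated weakly across features, which are not independent replicates. Between 4 h and 8 h r was 0.0860 in TMD8 and -0.118 in U2932, and between the lines it was 0.0611 at 4 h and 0.0873 at 8 h. YK-S minus DMSO and YK-R minus DMSO share the DMSO arrays, which alone gives a correlation, simulated at r = 0.50 for unchanged groups. At 4 h r was 0.856 with a covariance of 0.266, against 0.0394 simulated for unchanged groups, and 535 features were called as higher with both forms and 466 as lower, counts that the shared arrays raise by themselves. The simulation gave all groups the same spread, but for SPIB, IRF4, MYC and DHX9 the DMSO 4 h arrays varied more. Their SDs were 0.66, 0.50, 0.58 and 1.56 with DMSO, and 0.31, 0.22, 0.28 and 0.13 with YK-S. With YK-R the SDs were 0.13, 0.27, 0.18 and 0.071. A wider spread of the shared arrays raises r and covariance by itself, so the excess at 4 h does not show a response common to both forms. At 8 h r was 0.559 and the covariance was 0.0304, below the 0.0394 simulated. By the value table's names r was 0.494 at 4 h and 0.220 at 8 h, against 0.501 and 0.499 simulated, with a covariance of 0.0232 at 4 h and 0.00281 at 8 h against 0.0114 simulated for both. At 4 h under these names the measures differ, with r not above its simulated value and the covariance above it.

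The difference between times in solvent alone was read from U2932 DMSO arrays, 8 h minus 4 h, but brightness differs along with time. By the signal table's names 3 of 3 DMSO arrays at 4 h and 0 of 3 at 8 h are dim (2 and 0 by the value table's), so the values below cannot be put down to time. Under the signal table's names 902 features were called, 676 higher and 226 lower at 8 h. PDIA4 rose by 1.35 (SE 0.28), ETS2 by 1.31 (SE 0.25), TUBD1 by 1.20 (SE 0.28) and PRDM1 by 1.12 (SE 0.29), and TOP2A fell by 0.65 (SE 0.17). Median scaling in place of quantile normalization moved the median of all features by 0.65 in this comparison, by 0.46 in YK-S minus DMSO and by 0.64 in YK-S minus YK-R at 4 h. Relative to that shift TOP2A, at 1.48 with that scaling, was still higher, the opposite of its direction above. By the value table's names 195 features were called, 75 higher and 120 lower, and 7 of them were among the 902. There PDIA4 was at 0.0031, ETS2 at 0.020, TUBD1 at 0.51, PRDM1 at -0.0045 and TOP2A at -0.15, and none of these 5 was called.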

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

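The counts over other splits of the arrays are tests chosen after the results were seen; the tests of the differences between times were planned. In U2932, under the signal table's names, the effect of YK-S against DMSO differed between 8 h and 4 h for 82 features, 10 higher and 72 lower (3038 at an unadjusted p under 0.05), and a difference between groups is what singled out this result. The 5 largest increases of the effect were NBPF9 at log2 2.08 (SE 0.47), NMNAT1 at 1.94, ALKBH8 at 1.48, FAM184B at 1.39 and NELFB at 1.21, and the 5 largest decreases GALR2 at -2.41, MSRB2 at -2.37, SLAMF1 at -2.32, WWP2 at -2.27 and CASTOR3P at -2.23. Of 100 splits of the arrays 13 gave as many, the highest other count being 354, so chance is not excluded, and a split with several times the real count points to a structure of the samples. The count was 0 without DMSO 4 h replicate 2, 1392 without replicate 3, and 0 under the value table's names.

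For YK-R against DMSO the same difference between times was called for 198 features, 101 higher and 97 lower (3922 at an unadjusted p under 0.05). NBPF9 was at 2.58, HOXD3 at 2.26, ATP1B2 at 2.14, NBPF10 at 2.12 and MID1IP1 at 2.10, and BCL10 at -2.06, ASB16 at -1.98, RGS8 at -1.89, GOSR1 at -1.86 and ZNF543 at -1.86. HOXD3 lay above background on none of the YK-R arrays at 4 h, so its value rests on the background level. No bounds were computed for differences between times. Here 4 of 100 splits gave as many, a share under 0.05, but the highest other count was 351, and leaving out DMSO 4 h replicate 3 gave 3681 and YK-R 8 h replicate 1 gave 45. By the value table's names 6 were called. The groups at 4 h hold most of the dim arrays, so time and array brightness cannot be told apart in these counts, and no explanation was weighed for them apart from the naming and the dim arrays below.

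By list, the time difference of YK-S minus DMSO was lower for DNA replication, with a median of -0.31 (adjusted p = 0.031, and adjusted p = 0.75 with an estimated correlation), plasma cell genes at -0.36 (adjusted p = 0.031, and 0.20), the integrated stress response at -0.34 (adjusted p = 0.012, and 0.20) and the unfolded protein response at -0.30 (adjusted p = 0.031, and 0.20). Adjusted over the list alone, 6 plasma cell genes, 9 of the integrated stress response and 6 of the unfolded protein response fell. The mitosis list was higher in the time difference of YK-S minus YK-R in U2932, at 0.26 (adjusted p = 0.0061, and 0.99 with an estimated correlation).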

How the results depend on the processing

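The plain normexp correction, the fits without dim arrays and the medians over the C/D box snoRNAs are tests chosen after the data were seen. In TMD8 at 4 h and in YK-S minus DMSO, YK-R minus DMSO and YK-S minus YK-R in U2932 at 8 h, 0 features were called under every alternative run, including the fits without dim arrays for U2932. A fold minimum of 0.58 log2 kept all counts of features within 1.5 times. Leaving aside fits without 1 array, 155 counts or correlations of comparisons stayed within 1.5 times or within their spread, 56 moved further and 2 reversed. Of the values of single genes or lists 927 kept their direction and call (uncalled genes: stayed within 1 SE), 350 lost and 11 gained a call in the same direction, 66 reversed and 28 uncalled ones moved by more than 1 SE. A block for the slide was not run, since the labels give no slide. Signal over background limits the U2932 values at 4 h, where 25.2% of probes were detected on the dimmest array. Lists are counted below as pairs of a list and 1 of the 8 comparisons of treatments at 1 time in 1 line, without differences between lines or times and without DMSO over time; 5 such pairs were called. For the changes below, apart from FBXL6, the cause was not tested.

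With no background correction the counts were 2 for TMD8 YK-S minus YK-R at 8 h, 14 for U2932 YK-S minus YK-R at 4 h and 107 for the time difference of YK-R minus DMSO, and 10 lists were called in place of 5. Plain normexp gave 14 for U2932 YK-S minus YK-R at 4 h, 119 for the time difference of YK-R minus DMSO, and 8 lists. The mean of a gene's probes gave 6 for the time difference of YK-S minus YK-R in U2932 and 10 lists. An intensity trend with a robust prior gave 2, 21 and 102 for the time differences of YK-S minus YK-R, YK-S minus DMSO and YK-R minus DMSO in U2932. With no detection filter the counts were 298 for U2932 YK-S minus YK-R at 4 h, 48 and 13 for the time differences of YK-S minus YK-R and YK-S minus DMSO in U2932, and 14 lists were called. Camera with an estimated correlation called 0 of the 5 pairs, while outside them the p53 targets passed in the time difference in TMD8 (adjusted p = 0.047).

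The stricter detection filter gave 1 for TMD8 YK-S minus YK-R at 8 h, and in U2932 112 for YK-S minus DMSO, 752 for YK-R minus DMSO and 0 for YK-S minus YK-R at 4 h, 0 and 6 for the time differences of YK-S minus DMSO and YK-R minus DMSO, and 89 for DMSO over time. The correlation of YK-S minus YK-R at 4 h between the lines was 0.148 there. Each line on its own gave 13 for TMD8 at 8 h, and in U2932 0, 347 and 0 for the same 4 h comparisons, 0 and 0 for the same time differences, 0 for DMSO over time, and 10 lists. FBXL6 turned to 0.18 for both YK-S and YK-R minus DMSO at 4 h in that fit, where another probe stands for the gene.

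Median scaling moved the median of all features, by 0.46 in YK-S minus DMSO, -0.086 in YK-R minus DMSO and 0.64 in YK-S minus YK-R at 4 h in U2932, -0.72 in the line difference at 4 h, -0.76 and -0.51 in the time differences of YK-S minus YK-R and YK-S minus DMSO in U2932, and 0.65 in DMSO over time. It gave 65 (24 higher, 41 lower) for TMD8 YK-S minus YK-R at 8 h, 3151 (3150 higher), 0 and 0 for YK-S minus DMSO, YK-R minus DMSO and YK-S minus YK-R in U2932 at 4 h, 1 for the line difference at 8 h, 0 and 0 for the time differences of YK-S minus DMSO and YK-R minus DMSO, 9695 for DMSO over time (9692 higher), and 43 lists. Without allowing for the shift, the mitosis list turned to 1.05 for U2932 YK-S minus YK-R at 4 h, to -1.09 for the line difference at 4 h and to -1.33 for its time difference in U2932. TOP2A turned to 0.66 for YK-S minus DMSO at 4 h and 1.48 for DMSO over time, SPIB to 1.59 for DMSO over time, NELFB to -0.34 for the time difference of YK-S minus DMSO, and ELL2 to -0.024 for YK-R minus DMSO at 4 h; relative to the shift, NELFB and ELL2 stayed above 0. The correlation between times in U2932 was -0.435, that between lines at 4 h was -0.0442, and that of both forms against DMSO at 4 h was 0.523.

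The deposited log2 values, with their own names, gave 13 for TMD8 YK-S minus YK-R at 8 h, 0, 306 and 0 for the U2932 4 h comparisons in the order above, 2 and 10 for the line differences at 4 h and 8 h, 0 and 6 for the time differences of YK-S minus DMSO and YK-R minus DMSO, 195 for DMSO over time, and 9 lists. The correlation between lines at 4 h was -0.123, and those of both forms against DMSO were 0.494 at 4 h and 0.220 at 8 h. The immediate early list was at -0.014 with its camera direction reversed and the unfolded protein response list at 0.0080 for YK-R minus DMSO at 8 h. The mitosis list was at 0.19 for U2932 YK-S minus YK-R at 4 h, -0.057 for the line difference at 4 h and -0.049 for its time difference in U2932.

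With those names, the genes that the text names as called in YK-S minus DMSO at 4 h and that changed sign were WWP2 (-0.056), EFCAB14 (-0.034), ZBBX (0.0014) and PDIA4 (-0.054). For YK-R minus DMSO at 4 h they were BCL10 (-0.066), ZNF543 (-0.021), P2RY12 (-0.42), FERRY3 (-0.17), FBLN1 (-0.10), CCZ1B (-0.41), GPR18 (-0.36), RPRD1B (-0.21), ZBBX (0.47), FHIP2B (0.47), HOXD3 (0.37), CTDP1 (0.25), NRK (0.42), FBXW5 (0.010), GSDMA (0.58), MID1IP1 (0.20), FBXL6 (0.11), TUBE1 (-0.050), CDC25C (-0.080), CENPA (-0.0058), TOP2A (0.21), ETS2 (-0.15), GABPA (-0.020), FCGR2B (-0.14), PRDM1 (-0.066), CD38 (-0.27), ELL2 (-0.094) and EDEM1 (-0.34). For YK-S minus YK-R at 4 h they were MIR146A (-0.25), B3GLCT (-0.21), TBC1D9 (-0.12), C10orf88 (-0.15), MACO1 (-0.042), ATG9A (-0.32), OR11H1 (-0.22), TEF (-0.37), GDF11 (-0.062), SESN2 (-0.080), ANKRD24 (0.31) and RIMS4 (0.25). For DMSO over time PRDM1 was at -0.0045. For the time difference of YK-S minus DMSO NMNAT1 was at -0.0034 and WWP2 at 0.068, and for that of YK-R minus DMSO HOXD3 was at -0.26, ATP1B2 at -0.077, MID1IP1 at -0.11 and GOSR1 at 0.046.

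Leaving out each array in turn gave 0 to 0 features for TMD8 at 4 h and for the U2932 treatment comparisons at 8 h, and 0 to 124 for TMD8 at 8 h, the highest without YK-R 8 h replicate 2. In U2932 at 4 h the ranges were 195 to 6561 for YK-S minus DMSO and 928 to 7868 for YK-R minus DMSO, in both the lowest without DMSO 4 h replicate 2 and the highest without replicate 3, and 23 to 167 for YK-S minus YK-R, the highest without YK-S 4 h replicate 1. Line differences ranged from 0 to 3 at 4 h, the highest without U2932 YK-R 4 h replicate 1, and from 0 to 22 at 8 h, the highest without TMD8 YK-R 8 h replicate 2. Time differences ranged from 0 to 16 for YK-S minus YK-R in TMD8, the highest without that same array, and from 0 to 28 in U2932, the highest without YK-R 4 h replicate 1. They ranged from 0 to 1392 for YK-S minus DMSO, without DMSO 4 h replicate 2 and 3, and from 45 to 3681 for YK-R minus DMSO, without YK-R 8 h replicate 1 and DMSO 4 h replicate 3. DMSO over time ranged from 157 to 5120, again without DMSO 4 h replicates 2 and 3, and the lists called from 2 to 14, without DMSO 8 h replicates 1 and 3. The correlations ranged from -0.0397 to 0.190 between times in TMD8, -0.149 to -0.0442 between times in U2932, 0.0181 to 0.0808 between lines at 4 h and -0.0578 to 0.210 at 8 h, and for both forms against DMSO from 0.727 to 0.921 at 4 h and 0.412 to 0.714 at 8 h. Arrays of U2932 were left out by the signal table's names. Among single genes and lists, 234 values lost a call with 1 array left out and 758 did not change. Medians of lists ranged from 0.065 to 0.27 for mitosis in TMD8 at 8 h, -0.29 to -0.11 for the integrated stress response (YK-S minus DMSO, 8 h), -0.20 to -0.024 for immediate early genes and -0.26 to -0.045 for the unfolded protein response (YK-R minus DMSO, 8 h), and -0.32 to -0.18 for mitosis in U2932 YK-S minus YK-R at 4 h, which stayed called. The C/D box median in TMD8 in the fit of 30 arrays stayed between 0.010 and 0.093 at 4 h and between 0.20 and 0.30 at 8 h.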

Other observations

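The tests on a single array, on short RNAs, on the noise of dim arrays, on the naming of arrays and on other splits of the arrays were chosen after the results were seen; the tests on host genes and on probes near the background had their predictions written before. Heat shock genes were higher, by the value table's names, in U2932 DMSO arrays at 8 h than at 4 h, where 2 of 3 arrays are dim at 4 h and 0 of 3 at 8 h, so time and brightness are not separated, with 17 of 20 above 0 and a median of 0.36 (adjusted p = 5.5e-08, and adjusted p = 0.0059 with an estimated correlation), and 2 members rose, or 8 adjusted over the list alone. HSPA1B rose by 1.40 (SE 0.26, adjusted p = 0.019), against 0.90 under the signal table's names, and CHORDC1 by 1.09. Lower lists were immediate early genes at -0.16 (adjusted p = 1.5e-06, and 0.040 with an estimated correlation), NF-kB targets at -0.13 (9.5e-05, and 0.038), genes of the unfolded protein response at -0.17 (0.00093, and 0.040), GCB-type genes at -0.22 (0.00093, and 0.12), B cell receptor and identity genes at -0.20 (0.0017, and 0.036), hypoxia and glycolysis genes at -0.15 (0.0025, and 0.078), HLA class II genes at -0.16 (0.0027, and 0.040) and plasma cell genes at -0.085 (0.0084, and 0.078). CXCR5 was at -1.16, JUND at -1.05 and MYC at -0.98 (adjusted p = 0.0047). Under the signal table's names the heat shock median was 0.21 (adjusted p = 0.82), and none of the 29 lists was called in this comparison.

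For p53 targets the difference between the forms was called as changing with time in TMD8. The time difference of YK-S minus YK-R, 8 h minus 4 h, had a median of 0.21 with 16 of 23 above 0 (camera adjusted p = 0.026, and adjusted p = 0.047 with an estimated correlation). In the TMD8 fit the adjusted p with an estimated correlation was 0.18. Fits without 1 array were not run for this list. In TMD8 at 8 h the remaining lists were not called: interferon genes were at -0.092 (adjusted p = 0.14), p53 targets 0.14 (0.14), histones 0.074 (0.23), heat shock 0.075 (0.42), apoptosis 0.011, cholesterol synthesis 0.028, mRNA splicing -0.034, cytosolic ribosome -0.012, actin and SRF targets -0.0044, mitochondrial respiration -0.037, HLA class II -0.040, GCB-type 0.0062, immediate early -0.039, MYC targets 0.027, plasma cell -0.027, unfolded protein response 0.024, integrated stress response 0.0067, hypoxia and glycolysis -0.016, oxidative stress -0.12 (0.42), DNA replication -0.0049 and B cell receptor and identity -0.064 (0.82). In the TMD8 fit interferon genes were at -0.11 (adjusted p = 0.049, and adjusted p = 0.81 with an estimated correlation). In U2932 at 8 h the 12 snoRNAs called in TMD8 had YK-S minus YK-R above 0 for 12 of 12 under both namings, with medians of 0.43 and 0.31, while the whole C/D box class had medians of 0.094 (67 of 101 above 0) and 0.069 (69 of 101). For these 12, YK-S minus DMSO was above 0 for 5 of 12 (-0.033) and 12 of 12 (0.38), YK-R minus DMSO for 0 of 12 (-0.30) and 7 of 12 (0.021), and none of them was called. The namings cannot both be right, so the same sign under both is not repeated support. RNAs of a class may also vary together, so 12 signs are not 12 separate observations. With the value table and without dim arrays, tubulins were higher at 8 h in YK-S minus DMSO by 0.11 (adjusted p = 0.0021, and 0.53 with an estimated correlation) and in YK-S minus YK-R by 0.092 (0.00035, and 0.58), and the mitosis list by 0.17 (6.7e-10, and 0.39) and 0.12 (1.9e-08, and 0.50).

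In TMD8 at 8 h 12 of 101 C/D box snoRNAs were called as higher with YK-S in the fit of TMD8 alone and none in the fit of 30 arrays. A single array as the source of the median over the class is argued against by leaving out each of 6 arrays in the TMD8 fit, where the lowest median was 0.25, but the calls went to 0 without YK-S 8 h replicate 2. More transcript of the host genes, as read by the brightest probe of each, is argued against by a median of 0.0019 over 47 measured host genes (interval -0.017 to 0.046), while their 78 snoRNAs had a median of 0.24. That interval comes from resampling genes, so it does not measure the spread between arrays. Host RNA that still holds the snoRNA was not measured apart, so a change in it stays open. Better recovery of short RNAs in the YK-S extracts stays open, since other short non-coding RNAs had a median of 0.153, with 17 of 25 above 0, such as RMRP at 0.54 and RNVU1-7 at 0.41, and others at the opposite end, such as RNY4 at -0.68 and RNY1 at -0.61. A change in snoRNA processing or stability with either form may also underlie the difference and was not tested. TMD8 had no DMSO arrays, so it stays open whether YK-S raised the signal or YK-R lowered it.

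The calls of YK-R minus DMSO at 4 h in U2932, 3381 under the signal table's names, may come from noise of dim arrays, from probes near the background or from the treatment. Of 765 other kept probes of called genes, 66.0% moved in the direction of the called probe, which leaves noise open. Of the called features 29.5% were detected on all 6 arrays, against 37.6% of all features, which decides nothing either. Of the 8 genes named for this comparison that had another kept probe, 5 had one that moved the other way. By these names 5 of the 6 compared arrays had mean signals from 85.4 to 110.4 and the other, DMSO 4 h replicate 1, had 196.7, so no YK-R array is bright, and noise and an effect of the compound cannot be told apart.

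The tables give different names to the same U2932 arrays, and either naming may be wrong. By the signal table's names 6 of 18 arrays had a nearest neighbour of their own group (permutation p = 0.0347 over all names, 0.0918 within arrays of like brightness). By the value table's names it was 4 of 18 arrays (permutation p = 0.210 and 0.195). Of the 18 nearest neighbours 14 were of like brightness, so this test, which was changed after its first form was seen, does not settle which names are right. No biological explanation was tested for this pattern.

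With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest other were 0 and 0 for TMD8 YK-S minus YK-R at 4 h, 0 and 2 at 8 h, 1337 and 3463 for U2932 YK-S minus DMSO at 4 h, 0 and 0 at 8 h, 3381 and 2805 for YK-R minus DMSO at 4 h, 0 and 0 at 8 h, 27 and 564 for YK-S minus YK-R at 4 h, 0 and 0 at 8 h, and 902 and 2732 for DMSO over time. As many were given by 10, 10, 5, 10, 1, 10, 4, 10 and 2 of the 10 splits in that order, and the splits calling several times 1337, 27 and 902 point to a structure of the samples. For the differences with a real count of 0, 100 of 100 splits gave as many, which is fixed since no count is lower, so these splits decide nothing: the highest other counts were 19 and 0 for the difference between lines at 4 h and 8 h, and 4 and 63 for the difference between times of YK-S minus YK-R in TMD8 and U2932.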
